A study of Homo sapiens with 4 samples.

How the data were processed

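Total RNA from 4 cell cultures (Jeko-1, Jeko-1/R, Raji and Raji/R) was extracted with Trizol, and biotinylated cRNA was prepared from 6 µg, per the labels' protocols. The probe annotation names the array as the Affymetrix Human Genome U133 Plus 2.0, on which a gene is read by 1 or more probe sets. Signals were computed with MAS5, per the submitters' processing notes, and its version is not given in the sources used here. The authors deposited log2 signals for 54613 probe sets on each array. The log base was read from the values, since on base 2 the mean signal without the highest and lowest 2% was 497, 497, 494 and 494 on the 4 arrays, as scaling to a common target would give. Between 14 and 285 probe sets per array stood at a log2 value of 0. MAS5 scales each array by 1 factor, so differences between arrays that depend on signal level stay in the values. Detection calls were not used here.

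Probe sets were named through the platform annotation, and symbols were updated by gene ID with the RefSeq table of assembly GRCh38.p14. A single symbol was given for 41091 probe sets, several for 1801 and none for 11721; probe sets without a single symbol were not analysed here. Gene IDs of 41037 probe sets matched the RefSeq table, and 0 symbols changed. Of 1465 genes in the fixed lists, 1323 had a value. No probe set ID had the prefix of the array's control probe sets, so ratios of 3' to 5' control probe sets were not analysed here. Array medians, quartiles and totals were computed, but they do not measure RNA degradation. RNA quality was therefore not checked.

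Groups were taken from the labels. The pooled median of all values, a log2 of 6.28 or a signal of 77.5, served as a floor, and lower values were raised to it. A gene was represented by its probe set with the highest mean signal over the 4 arrays. Within a line, genes with at least 1 array at or above the floor were described by the ratio of resistant over parental signal, with 2-fold as the size that counted as changed. A ratio with 1 side below the floor is a lower bound and is written "at least". The overlap between lines was set beside the overlap of independent lists. There were 1 array per group and no replicates, so no gene was tested and no p-value was computed within a line. The ranking of gene lists within a line, described below, reflects spread between genes and not between cultures. Between states, limma 3.58.1 (R 4.3.3) was fitted with cell line and resistance as terms, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment, two-sided, over 15575 genes. The pairing comes from the cell lines, since each resistant line was derived from its parent. An exact test over 2 pairs could not give a two-sided p below 0.5. Nothing in the labels describes separate cultures of a group.

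Before the data were examined, 54 gene lists were fixed. The median of a list was ranked among those of 10000 random lists of the same size, matched on mean expression in 20 bins, and camera was run on the limma fit. Named genes followed a rule set at the same time. In each line these were MS4A1, the 8 largest increases and 8 largest decreases above the floor on both arrays, the 4 largest on each side with 1 value below the floor, and up to 4 changed members of each list. Over both lines they were up to 10 genes changed the same way per direction, the 6 largest opposite changes, and the 5 lowest p per direction. Genes with another probe set changed 2-fold the opposite way and immunoglobulin variable segments were left out. The rule gave 136 genes; the text names a part of them, picked after their values were seen, and the others are not reported here. Outside this rule, CCND1, SOX11, CD55, CD46 and BCL2 were named after their values were seen, and the closing section gives all genes that changed in opposite directions. Each named list and gene was also examined under alternative scalings, floors and choices of probe set. A lowess adjustment (fraction 0.3) of the ratio on mean signal, and the comparison with the 5 genes nearest in signal, were added after seeing the data.

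Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The steps were tested on simulated data made from the real levels and the spread fitted by limma, with 200 genes changed. The changed genes were drawn only from genes well above the floor on all 4 arrays, so recovery near the floor was not tested. The 2-fold count recovered 53.5% of genes changed 2-fold and 98.5% of those changed 4-fold among 11588 genes of Jeko-1, and called 362 and 375 unchanged genes. For 14642 genes of Raji it recovered 55.5% and 98.0%, with 415 and 423 unchanged genes called. This simulation gave both lines the same spread, while the real log2 ratios had an SD of 0.28 in Jeko-1 and 0.53 in Raji. The 362 unchanged genes called for Jeko-1 exceed the 113 genes that changed in the real pair. These rates are therefore not error rates of the real pairs. Of 200 random lists of 25 genes, 5.0% in Jeko-1 and 5.5% in Raji lay outside the central 95%.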

Results

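Gene expression was measured in 2 human B-cell lymphoma lines and in a rituximab-resistant subline of each. Jeko-1 is a mantle cell lymphoma line and Raji is a Burkitt lymphoma line. Rituximab is an antibody against CD20, a surface protein of B cells that is encoded by MS4A1. The sublines Jeko-1/R and Raji/R were set against their parental lines to look for expression changes that accompany resistance. There were 4 oligonucleotide arrays, 1 for each parental and each resistant line, so no group had a replicate. The number of arrays limits the precision, and no p-value is given within a line. Each array held 54613 probe sets, and 19775 genes were represented by a probe set with a single gene symbol. As a stand-in for error, the log2 ratios of different probe sets of the same gene varied with an SD of 0.25 in the Jeko-1 pair (5310 genes) and 0.49 in the Raji pair (4949 genes). This spread covers differences between probe sets and not differences between cultures.

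The lines kept their identity. Among 1082 genes at least 8-fold apart between the parental lines, 1080 in Jeko-1/R and 1078 in Raji/R were nearer to their own parent (99.8% and 99.6%). CCND1 and SOX11, genes that are typically high in mantle cell lymphoma, had signals of 15834 and 9180 in Jeko-1 and of 14973 and 8158 in Jeko-1/R. In Raji and Raji/R, CCND1 stood at 6.44 and 35.1 and SOX11 at 6.15 and 14.6, below the signal floor of 77.5. The median log2 signal was 6.11 in Jeko-1, 6.12 in Jeko-1/R, 6.18 in Raji and 6.59 in Raji/R. On the Raji/R array 55.6% of the probe sets reached the floor, against 48.0%, 48.1% and 48.3% on the other arrays. Pearson's r across all probe sets, which are not independent replicates, was 0.933 for the Jeko-1 pair and 0.859 for the Raji pair.

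The first comparison concerned the target of the antibody. MS4A1 was abundant on every array and differed little between resistant and parental cells. Its brightest probe set gave a signal of 24891 in Jeko-1 and 23236 in Jeko-1/R, a log2 ratio of -0.10. In Raji and Raji/R it gave 11514 and 11698, a log2 ratio of 0.02. Over all 4 probe sets of MS4A1 the log2 ratio averaged -0.19 ± 0.10 (SD between probe sets) in Jeko-1/R and 0.22 ± 0.28 in Raji/R. The largest single value was 0.62, from a dimmer probe set in Raji/R. No MS4A1 probe set reached a 2-fold difference in either line.

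The second comparison was Jeko-1/R against Jeko-1. Few genes differed by 2-fold or more, and the lower genes included interferon-stimulated, hypoxia-related and heat shock genes. Of 11588 genes above the floor on at least 1 array of the pair, 44 were at least 2-fold higher and 69 at least 2-fold lower in Jeko-1/R, which is 0.975% of the genes. The interferon-induced gene IFI44L had the largest measured decrease, from 935 to 206 (log2 ratio -2.18), and IFI44 was next, from 391 to 99.6 (-1.97, with -0.97 from its other probe set). IFI27, also induced by interferon, was at least 4.27-fold lower, with the resistant value below the floor. ADM, the gene of the vasodilator peptide adrenomedullin, had a log2 ratio of -1.88, the same to 2 decimals as the inducible heat shock gene HSPA6. The metallothionein gene MT1H stood at -1.73, the collagen-processing enhancer PCOLCE at -1.58, the phospholipid scramblase PLSCR1 at -1.49 (other probe set -0.87) and the histone gene H2BC3 at -1.49. Among genes higher in Jeko-1/R, PHEX, a membrane peptidase gene, had the largest measured ratio (1.67), although its other probe set above the floor gave 0.12. It was followed by CASTOR2, an arginine-sensor family member of the mTORC1 pathway (1.55), LYSMD4 (1.47), RASGRP1, a Ras activator of lymphocytes (1.41), BAIAP2L1 (1.39), the adhesion receptor ADGRG1 (1.37) and MYLK3 (1.36). Other probe sets of MYLK3 gave 1.48 and 1.67.

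Gene lists fixed beforehand described these changes in Jeko-1/R. For each list the median log2 ratio was set beside the central 95% of medians of 10000 random lists of the same size and expression. Of 54 lists, 8 lay below that range and 3 above it in Jeko-1/R, where chance would place 2.70 outside. This figure takes the members of a list to vary independently. Members that move together would place more lists outside. Glycolysis genes had a median of -0.53 (random range -0.10 to 0.08), which was -0.32 with the floor at the 75th percentile and -0.34 with the mean of probe sets. Of 25 measured members, 23 were below 0 and 3 were at least 2-fold lower, among them the glucose transporter SLC2A3 (-1.08, with -0.86 and -0.76 from other probe sets) and the aldolase gene ALDOC (-1.04). The regulatory kinase gene PFKFB4 was at least 4.21-fold lower. Hypoxia genes had a median of -0.49 (random range -0.10 to 0.08), with 20 of 22 members below 0 and 3 at least 2-fold lower: ADM, the prolyl hydroxylase gene P4HA1 (-1.35) and ANKRD37 (-1.08). The glycolysis and hypoxia lists shared 0 genes. Interferon-stimulated genes had a median of -0.35 (random range -0.09 to 0.12), with 25 of 34 below 0 and 4 at least 2-fold lower, of which IFI6 (-1.17) had the smallest change. Only 11 of 20 other probe sets of these interferon-stimulated genes moved down, and with the floor at the 75th percentile the median was -0.07, inside the random range. Replication-dependent histones stood at -0.36 (range -0.14 to 0.11), DNA replication genes at -0.17 (range -0.07 to 0.06), heat shock genes at -0.22 (range -0.12 to 0.08) and mitotic genes at -0.09 (range -0.08 to 0.04). Heat shock members included DNAJB1 (-1.25) and HSPB1 (-1.09). The heat shock median lay inside its random range with a pseudocount (-0.10) and without x_at and s_at probe sets (-0.08), and the mitotic median with the higher floor (-0.07) and without those probe sets (-0.08). The list of fatty acid and lipid metabolism stood at -0.11 (range -0.10 to 0.09), but inside its range with quantile normalization (-0.10) and with the mean of probe sets (-0.03). Higher lists were the unfolded protein response (0.08, range -0.09 to 0.04), B-cell receptor signalling (0.11, range -0.08 to 0.08) and MHC class I (0.07, range -0.10 to 0.07), and none of these had a member changed 2-fold. B-cell receptor signalling lay inside its range with the mean of probe sets (0.05) and without x_at and s_at probe sets (0.02), and MHC class I without those probe sets (0.11). MHC class I and the unfolded protein response also lay inside the range of random lists not matched on expression, and with quantile normalization both stood at 0.13.

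**Figure D1:**
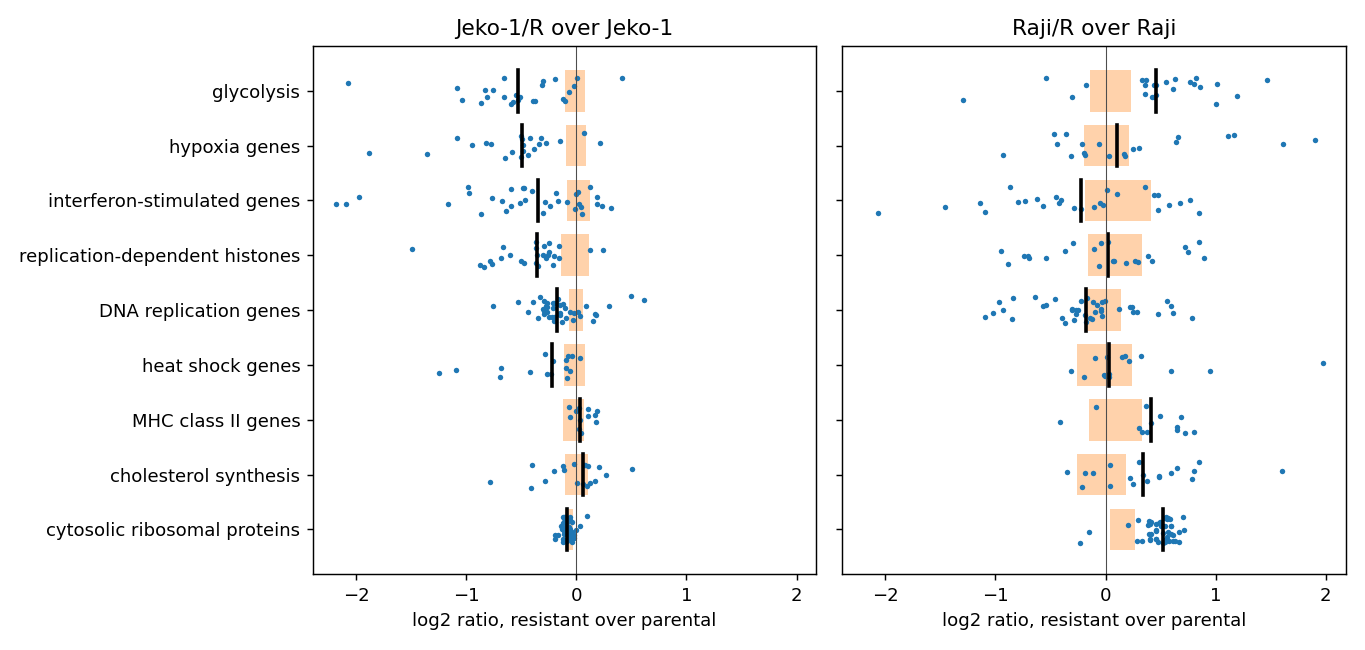
Log2 ratio of resistant over parental cells for the members of 9 gene lists, Jeko-1 pair on the left and Raji pair on the right. Each blue point is a gene, the black bar is the list median and the orange box is the central 95% of medians of matched random lists. Glycolysis medians were -0.53 in Jeko-1/R and 0.46 in Raji/R.

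The third comparison was Raji/R against Raji. More genes passed 2-fold than in the other line, and most of them had low signals. Of 14642 genes, 1026 were at least 2-fold higher and 386 at least 2-fold lower, so that 72.7% of the changed genes were higher. Of these 1412 changed genes, 703 were above the floor on both arrays, and the others had 1 value below it. With quantile normalization of the arrays the counts were 853 higher and 739 lower (53.6% higher), and with a signal-dependent loess adjustment, chosen after the data were seen, they were 634 and 575 (52.4%). With the floor at the 75th percentile the split turned, with 53 higher and 86 lower (38.1% higher). The 2928 genes with a mean signal between 106 and 204 had a median log2 ratio of 0.51 and held 830 of the 1026 higher genes. This group takes in many genes with 1 value raised to the floor. Genes with a lower mean could not reach 2-fold, and 0 of them did. HSPA6 had the largest measured ratio, from 160 to 1777 (3.47), and its other probe set gave 2.94. The growth factor GDF15, a stress-induced secreted protein, stood at 2.61, with 1.11 from its other probe set. PGAP6 (2.48), the circadian repressor CRY2 (2.20) and the basement membrane proteoglycan AGRN (2.16) followed, and the other probe set of PGAP6 gave 0.32 and those of AGRN 0.35 to 1.29. LCE1E (2.40) had another probe set at -0.25. CXCR1, a chemokine receptor gene, was at least 6.12-fold higher from a value below the floor. Among lower genes, MAP3K7CL stood at -2.21, the interferon-induced IFIT2 at -2.06, SLX4IP at -2.06 (other probe set -0.47) and SNAPC4 at -2.03 (other probe set -0.57). The axon guidance receptor gene ROBO1 was at least 5.10-fold lower, and TNFAIP8L2 at least 4.25-fold lower. PAX5, a transcription factor of B-cell identity, went from 13252 to 5628 (-1.24).

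**Figure D2:**
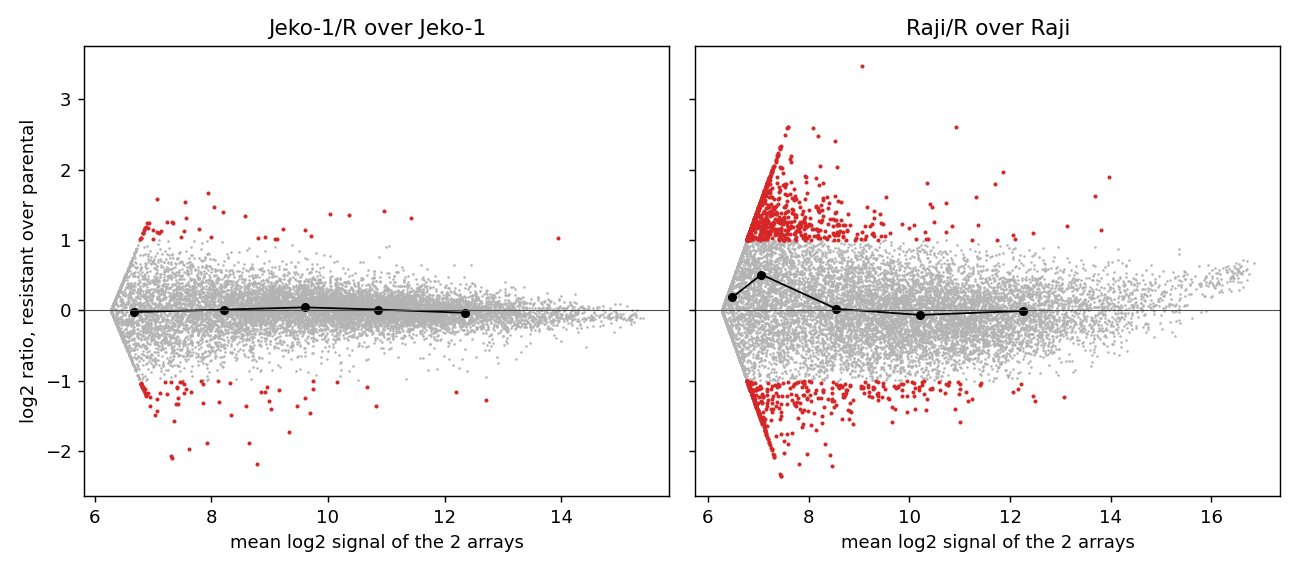
Log2 ratio of resistant over parental cells (vertical) against the mean log2 signal of the pair's 2 arrays (horizontal), 1 point per gene; red points are genes changed at least 2-fold and black circles are medians of 5 equal groups of genes by signal. In the Raji pair the highest of these medians was 0.51, while all 5 medians of the Jeko-1 pair lay between -0.03 and 0.04.

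In Raji/R, 6 of 54 lists lay above the central 95% of random lists and 3 below, where chance would place 2.70 outside if list members varied independently. Glycolysis genes had a median of 0.46 (random range -0.14 to 0.23), which was 0.30 with quantile normalization. Of 24 measured members, 20 were above 0 and 4 were at least 2-fold higher, among them SLC2A3 (1.46, with 0.67 and 0.68 from other probe sets), ALDOC (1.19) and the phosphofructokinase gene PFKL (1.02, with 0.26 from another probe set). The hexokinase gene HK2 went the other way, from 3573 to 1457 (-1.29), with other HK2 probe sets at -0.97 and -0.15. MHC class II genes stood at 0.41 (range -0.15 to 0.33, and 0.26 with quantile normalization), with 11 of 13 members above 0 and 0 changed 2-fold. The genes nearest to the MHC class II list in signal had a median of 0.18. Cholesterol synthesis stood at 0.34 (range -0.26 to 0.19), with TM7SF2 at 1.60. Without x_at and s_at probe sets the cholesterol median was 0.04, inside its random range. B-cell surface molecules other than CD20 stood at 0.23 (range -0.16 to 0.20), with LY9 at 1.81 and FCER2, the CD23 gene, at 1.42 (other probe set 0.70). The other LY9 probe sets gave 0.08 and 0.24. The surface molecule list lay inside its range without x_at and s_at probe sets (0.21). With random lists not matched on expression the surface molecule, cholesterol and MHC class II lists all lay inside their ranges. Cytosolic ribosomal protein genes stood at 0.52 (range 0.04 to 0.27), with 46 of 48 above 0. The non-ribosomal genes nearest to them in mean signal had a median of 0.53, and with quantile normalization the ribosomal median was -0.002. Interferon-stimulated genes stood at -0.22 (range -0.18 to 0.41), with 4 members at least 2-fold lower: IFIT2, PARP9 (-1.45, with -0.56 from another probe set), TRIM22 (-1.14) and IFIT3 (-1.10, with 0.13 from another probe set). Only 4 of 14 other probe sets of this list moved down, and 4 of 9 alternative settings kept the list below its random range. Fatty acid and lipid metabolism (-0.19, range -0.16 to 0.25) and chromatin modifiers (-0.24, range -0.21 to 0.17) also lay low. With the mean of all probe sets of a gene these medians were -0.07 and 0.08, inside their ranges. The genes nearest in signal had medians of 0.04 for the fatty acid list and -0.13 for the chromatin list. Fatty acid and lipid metabolism also lay inside its range with the higher floor (-0.19). DNA replication genes had a median of -0.17 in Raji/R too, just inside the random range of -0.18 to 0.14, and 6 of 9 alternative settings placed them below it. Hypoxia genes had a median of 0.10 (-0.19 with the higher floor), inside the random range of -0.20 to 0.22, although 4 members were at least 2-fold higher: HILPDA (1.90), ANKRD37 (1.61), BHLHE40 (1.16, with 0.57 from another probe set) and NDRG1 (1.11).

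Some markers of other cell types reached the floor on at least 1 array of a pair. Of 19 T-cell markers 8 did so in the Jeko-1 pair and 10 in the Raji pair, and of 24 myeloid markers 4 and 13. Of 15 NK-cell markers 1 reached it in the Jeko-1 pair and 7 in the Raji pair. T-cell, NK-cell and myeloid markers lay inside their random ranges in Jeko-1/R and Raji/R, and so did epithelial and stromal markers. The NK-cell result in Jeko-1/R rests on 1 gene and says little. In Raji/R 2 T-cell, 1 NK-cell, 2 myeloid and 3 epithelial and stromal markers were at least 2-fold higher, and 0 were 2-fold lower. The signals of these higher markers on the Raji/R array lay between 170 and 381. Among all genes of the Raji pair with a mean signal between 106 and 204, 830 of 2928 were higher and 218 lower. The marker counts are therefore not read as a gain of other cell types. In Raji/R the 8 measured erythroid and megakaryocyte markers had a median of 0.83 (range -0.26 to 0.51). The platelet integrin gene ITGA2B went from 117 to 277, and GP9 was at least 2.03-fold higher, at 157. The genes nearest to the erythroid and megakaryocyte list in signal had a median of 0.19. The list lay inside its random range with the floor at the 75th percentile (0.55), with a pseudocount (0.72) and with the mean of probe sets (0.39). Complement regulators, which protect cells from antibody-directed complement, had medians of -0.13 in Jeko-1/R (range -0.25 to 0.21) and 0.06 in Raji/R (range -0.24 to 0.48). Of 12 complement regulators, 5 were measured in the Jeko-1 pair and 11 in the Raji pair. Anti-apoptotic genes had medians of -0.01 (range -0.16 to 0.13) and -0.13 (range -0.36 to 0.32). Neither list had a member changed 2-fold, and CD55 stood at 0.10 and -0.22, CD46 at -0.13 and -0.22 and BCL2 at -0.10 and -0.38 in Jeko-1/R and Raji/R.

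The fourth comparison asked which genes changed the same way in both lines. Of 10655 genes measured in both pairs, 4 were at least 2-fold higher in both sublines, where independent lists would share 1.40, and 3 were at least 2-fold lower in both, where 1.75 would be shared. The higher genes were GTF2IP12 (1.31 in Jeko-1/R and at least 3.07-fold in Raji/R), REEP2, which stood below the floor in both parents (at least 2.21-fold and 4.42-fold), PTGDS (at least 2.25-fold in Jeko-1/R and 1.47 on the log2 scale in Raji/R) and NACA4P (1.03 and 1.62). GTF2IP12 and NACA4P are pseudogenes, and the other PTGDS probe sets gave -0.97 and 0.07 in Raji/R. The lower genes were the zinc finger genes ZNF521 (-1.12 and -1.29, with 0.05 and -0.80 from its other probe set) and ZNF76 (at least 2.56-fold lower in Jeko-1/R and -1.13 in Raji/R) and the channel gene HCN3 (at least 2.12-fold and 2.08-fold lower). NACA4P and PTGDS were read by x_at probe sets, and REEP2, ZNF76 and HCN3 by s_at probe sets. Such probe sets may also bind transcripts of other genes. Without x_at and s_at probe sets 2 genes were higher in both lines and 1 was lower. Another 11 genes passed 2-fold in opposite directions. Of these, 10 were lower in Jeko-1/R and higher in Raji/R, where independent lists would share 2.85. The expected overlaps take genes to vary independently and are not matched on signal level. The 10 genes included HSPA6 (-1.88 and 3.47), DNAJB1 (-1.25 and 1.97), the G-protein regulator RGS1 (-1.27 and 1.79), PCOLCE (-1.58 and 1.26) and SLC2A3. ADGRG1 was higher in Jeko-1/R (1.37) and at least 3.78-fold lower in Raji/R. Across genes, which are not independent replicates, Pearson's r between the log2 ratios of both lines was -0.027.

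**Figure D3:**
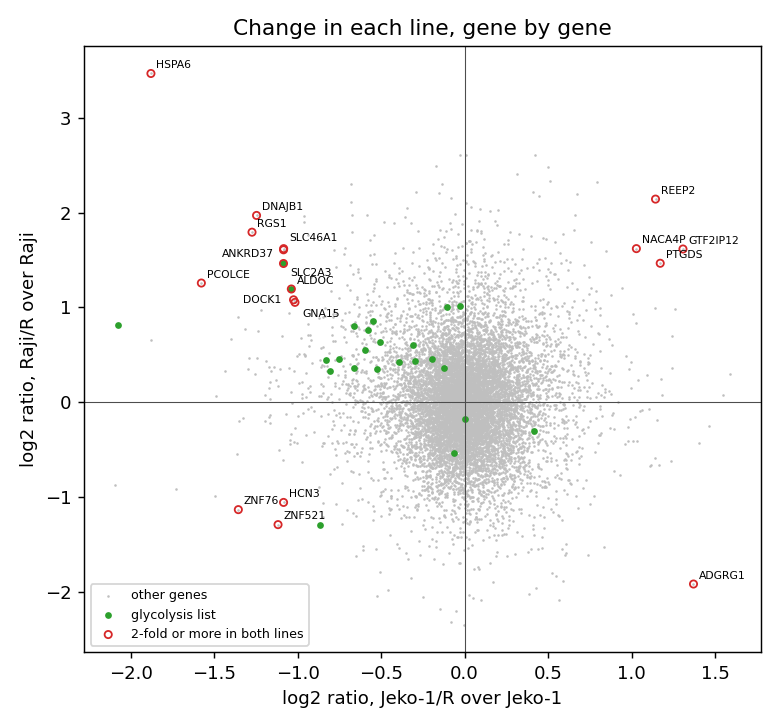
Log2 ratio in the Jeko-1 pair (horizontal) against that in the Raji pair (vertical), 1 point per gene measured in both. Red circles are the 18 genes changed at least 2-fold in both lines, and green points are glycolysis genes. Of the circled genes, 4 lie at upper right, 3 at lower left and 11 in opposite directions.

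With the 2 lines as replicates (n = 2 per state, 1 residual degree of freedom), p-values of the limma fit measure only the spread between these samples. In this fit limma called 0 of 15575 genes at an adjusted p of 0.05, while 324 had an unadjusted p below 0.05. The lowest adjusted p was 0.974, or 0.211 with a trend in the variance prior. None of the fixed lists had a member called when p was adjusted over the list alone, and 0 were called over all genes. The genes with the lowest p were GTF2IP12, REEP2, PTGDS, NACA4P and DNAL4 on the higher side and ZNF76, ZNF521, PLSCR1, MT1H and HCN3 on the lower side. PLSCR1 stood at -1.49 and -0.99, and MT1H at -1.73 and -0.91, in Jeko-1/R and Raji/R. In simulated data, with changes placed on genes well above the floor, the same fit recovered 0% of genes changed 2-fold or 4-fold in both lines and 96.5% of those changed 8-fold. Camera compares the members of a list with the other genes. With the correlation between members preset at 0.01, which was assumed, its p-values measure spread between genes and not between the 2 lines. Among 53 lists, camera in this setting placed 6 at an adjusted p below 0.05. These were interferon-stimulated genes (adjusted p = 1.05e-05), replication-dependent histones (0.000649), DNA replication genes (0.000965), hypoxia genes (0.00758) and mitotic genes (0.0145) on the lower side and cytosolic ribosomal proteins (0.00758) on the higher side. Not all were shared by the lines. Ribosomal genes had a median of -0.09 in Jeko-1/R, with 45 of 48 below 0, against 0.52 in Raji/R. Hypoxia genes had medians of -0.49 in Jeko-1/R and 0.10 in Raji/R, and histones of -0.36 and 0.03. Interferon-stimulated, DNA replication and mitotic genes had medians below 0 in both lines. With an estimated correlation every list had a camera adjusted p = 0.968, and 0 lists were called. In that setting both the correlation and the p-values rest on the 1 residual degree of freedom, where hardly any list could be called. The absence of calls therefore decides nothing about the lists.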

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

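The results below changed in opposite directions in the 2 lines. The difference between the lines was not tested, since each line had 1 pair of arrays. The comparison with genes nearest in signal, the loess adjustment and the tests on x_at and s_at probe sets were chosen after the result was seen.

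The difference of log2 ratios, Raji minus Jeko-1, was 5.35 for HSPA6, 3.22 for DNAJB1, 3.07 for RGS1, 2.83 for PCOLCE, 2.70 for SLC46A1, 2.69 for ANKRD37, 2.55 for SLC2A3, 2.23 for ALDOC, 2.11 for DOCK1 and 2.07 for GNA15. For ADGRG1 it was -3.29. The values of SLC46A1 and ADGRG1 rest on a signal below the floor in at least 1 resistant or parental array and are bounds.

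Glycolysis genes differed by 0.98 between the lines, with a median of -0.53 in Jeko-1/R and 0.46 in Raji/R. A scaling difference that depends on signal level is argued against, because the medians were -0.53 and 0.37 after loess adjustment and the genes nearest in signal had medians of -0.04 in Jeko-1/R and 0.06 in Raji/R. Cross-hybridising x_at and s_at probe sets are argued against, because without them the medians were -0.38 in Jeko-1/R and 0.44 in Raji/R, with 13 members each. A few other cross-hybridising probe sets stay open: 23 of 29 other probe sets in Jeko-1/R and 26 of 34 in Raji/R had the direction of the list, and the lower share, 76.5%, is known only to within 13.8 percentage points (0.5 of the width of the 95% Wilson interval), and leaving out the 5 members furthest in the list's direction as well gave -0.12 and -0.055, a step that moves any median toward 0 and decides nothing. A difference in culture density, oxygen or medium between the arrays of a pair may also give such changes, and so may resistance itself; with 1 culture per group these were not tested.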

How the results depend on the processing

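Of the medians of lists outside the random range in a line, 126 values under alternatives stayed within the SD of random lists, 32 moved further with the sign kept and 2 changed sign. Of medians inside the range, 12 changed sign and moved by more than that SD, among them cholesterol synthesis in Jeko-1/R (-0.15 with the mean of probe sets, below its random range), B-cell receptor signalling in Raji/R (0.04 without x_at and s_at probe sets) and hypoxia genes in Raji/R. At least 1 alternative placed another 12 lists outside the random range in Jeko-1/R and 13 in Raji/R, T-cell and NK-cell markers among the former and NK-cell markers among the latter. For named genes changed 2-fold, against the SD between probe sets, 887 values stayed, 268 moved with the sign kept and 3 changed sign. Glycolysis in both lines, and hypoxia genes, histones and DNA replication genes in Jeko-1/R, stayed outside the random range under all 9 alternatives. Counts of changed genes depended on the floor and the fold, since many genes lay near the floor of 77.5. The loess adjustment was chosen after the data were seen. Genes higher in Jeko-1/R numbered 29 with quantile normalization, 566 with a floor at the 25th percentile, 10 at the 75th, 604 with a pseudocount, 16 with the mean of probe sets, 0 at 4-fold and 311 at 1.5-fold. Genes lower in Jeko-1/R numbered 723 and 16 with the lower and higher floor, 682 with a pseudocount, 30 with the mean of probe sets, 44 without x_at and s_at probe sets, 3 at 4-fold and 390 at 1.5-fold. Genes higher in Raji/R numbered 3194 and 53 with the lower and higher floor, 2846 with a pseudocount, 537 with the mean of probe sets, 634 after loess, 35 at 4-fold and 2735 at 1.5-fold. Genes lower in Raji/R numbered 739 with quantile normalization, 1612 and 86 with the lower and higher floor, 1392 with a pseudocount, 181 with the mean of probe sets, 12 at 4-fold and 1532 at 1.5-fold. With the higher floor 38.1% of the changed Raji genes were higher, against 72.7% in the analysis above. Genes higher in both lines numbered 174 and 1 with the lower and higher floor, 173 with a pseudocount, 2 without x_at and s_at probe sets, 0 at 4-fold and 60 at 1.5-fold, and genes lower in both numbered 93, 0, 76, 1, 0 and 32. Genes lower in Jeko-1/R and higher in Raji/R numbered 6 with quantile normalization, 221 and 3 with the lower and higher floor, 170 with a pseudocount, 5 with the mean of probe sets, 0 at 4-fold and 91 at 1.5-fold, and the reverse numbered 2, 72, 0, 70, 0, 0 and 35. Nearness to the own parent was 100% in both lines for genes 16-fold apart and 98.5% in Raji/R for genes 4-fold apart. After loess 5 lists lay above the random range in Jeko-1/R. With random lists not matched on expression 3 lists lay above it and 6 below it in Raji/R. Among values outside the random range or changed 2-fold, the sign turned for ribosomal proteins in Raji/R with quantile normalization (-0.0022), for chromatin modifiers in Raji/R with the mean of probe sets (0.0823), and without x_at and s_at probe sets for LCE1E (-0.25), MCM10 (0.20) and TPM1 (-0.26) in Raji/R. The cause of these changes was not tested. Without cell line as a block for the pairing limma called 0 genes, and it called 0 in every other setting. Leaving out a pair was not run, since it leaves no residual degree of freedom.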

Other observations

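Some genes passed 2-fold while the median of their list stayed inside the random range. In Raji/R the immediate-early genes FOS and EGR1 stood at 1.35 and 1.21, and in Jeko-1/R at 0.54 and 0.76; the other EGR1 probe sets gave 1.15 and 1.34 in Raji/R and 0.88 and 1.12 in Jeko-1/R. JUN, another gene of that list, stood at -1.29 in Jeko-1/R, with other probe sets at -0.93 and -0.20. The NOTCH target NRARP stood at 1.89 in Raji/R, and the NOTCH ligand JAG1 at -1.17 in Jeko-1/R, with other probe sets at -1.44 and -0.56. The mitotic kinesin KIF11 stood at -1.65 and the checkpoint kinase BUB1B at -1.02 in Raji/R, while the proliferation marker MKI67 of the same list stood at 1.01, with other probe sets at -0.12 to 0.22. Of the chromatin modifiers, a list that lay below its random range, the deacetylase HDAC5 stood at 1.92 in Raji/R (other probe set -0.45), the methyltransferase EZH2 at -1.05 and HDAC9 at -1.27 (other probe sets -0.02 to 0.78). The transcriptional inhibitor ID2 stood at -1.16 in Jeko-1/R, and its other probe set gave -1.25. HK2 gave lower values in both lines, at -0.87 and -1.29, but its other probe sets gave 0.19 and 0.73 in Jeko-1/R.

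Of the tests below, the loess test of the split of changed genes and the comparison with genes nearest in signal were chosen after the result was seen.

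More genes were higher than lower in Raji/R, and more genes changed there than in Jeko-1/R. The split turned with the floor at the 75th percentile, where 38.1% of changed genes were higher, against 72.7% with the floor used. After loess adjustment 52.4% were higher, but this adjustment centres the ratios at every signal level, so the value decides nothing about the cause. The excess of higher genes lay mostly at low signals. Genes with a mean signal between 106 and 204 held 830 higher and 218 lower genes. In the groups of higher signal the counts were 161 and 106, 22 and 51, and 13 and 11. The lower quartile of log2 signal was 4.31 in Raji and 4.74 in Raji/R, and the upper was 8.28 and 8.36. Whether the array or the cells gave this difference at low signal stays open. Larger measurement error on the Raji arrays is a candidate explanation for the number: 63.1% of 805 other probe sets of changed genes moved the same way (95% Wilson interval 59.7 to 66.4%), against 77.8% of 54 in Jeko-1/R, and the spread between probe sets was 1.94 times as large. The share of 63.1% lay below the 65% that was set beforehand, but the upper end of its interval passes that bound. The share alone is therefore not decisive. The spread goes with larger error too. In the Raji pair the SD between probe sets was 0.49, against 0.53 for log2 ratios of genes above the floor on both arrays. In the Jeko-1 pair these values were 0.25 and 0.28. A larger response of Raji cells stays open and was not tested.

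The higher ribosomal protein genes in Raji/R may reflect their signal level and not a change of ribosomal genes as such. The 46 non-ribosomal genes nearest in mean signal had a median of 0.53, against 0.52 for the 48 ribosomal genes. A loess adjustment over the whole signal range lowered the ribosomal median to 0.26. This decides neither way, since it passes the bound of 0.25 by less than its spread (SD 0.05 of random lists). The bound was set before this test, but the loess adjustment itself was added after the data were seen. The ribosomal list stayed above its random range after loess, and 8 of 9 alternatives kept it there. That count says little about signal level, since the lower and higher floors left the median at 0.52. The exception was quantile normalization, which acts on signal level and gave -0.002, inside the random range.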
